A study of Homo sapiens with 17 samples.

How the data were processed

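Pull-downs with an m6A antibody and with IgG were sequenced in vehicle-treated HPr1AR, LNCaP and 22Rv1 cells. The 17 samples were put into 6 groups by cell line and antibody from their labels, before the data were examined. All groups held 3 samples except the m6A group of 22Rv1, which held 2; the sample with replicate number 2 of that group is not among the labels, and whether it entered the deposited 22Rv1 table is not known. The labels do not say that the replicates came from separate cultures. Sample descriptions name files in an order that conflicts with the titles, and were not used.

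The authors deposited 1 table per line, in which each line is a region made of neighbouring windows, with log2 fold values, p-values and adjusted p-values per region, and the gene names and exon, intron and promoter marks that overlap it. The file names give the line, and the headers give a log2 fold and p-value per region and the windows up and down in it. They do not say which samples entered the comparison or which pull-down is the numerator. The submitters' processing notes name hg38 as the genome build, which the region positions did not match. The aligner, the window counter and the test are not given in the sources used here. No column holds a value per sample, and 0 columns of that kind were left unused, so no leave-one-out fit and no estimate of the spread between samples was made. P-values of the authors' test are theirs. The binomial p-values computed here measure counting error within a table only. Those of Fisher's exact test and the exact McNemar test take regions or genes as independent units, which was not shown. None of them measures the spread between samples.

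The design was written for the authors' calls, with an adjusted p threshold of 0.05. The deposited log2 fold was found to follow log2(a + prior) minus 2 times log2(b + prior) plus a constant, with a and b whole reads in numerator and reference. The p-value followed the matching likelihood ratio test only after its statistic was multiplied by a fitted scale. This scale was 0.831 in HPr1AR, 0.820 in LNCaP and 0.9999 in 22Rv1. The constants were fitted on regions of 1 window with up to 3 numerator reads, where the p-value set the number of numerator reads. For every region, a and b were then sought as whole numbers that give its fold, for up to 150 numerator reads. Its -log10 p could be at most 1.35 times the predicted value. With log10 of its number of windows added, it had to reach 0.75 times that value. Over the 4647 fitted regions of HPr1AR, 3427 of LNCaP and 1018 of 22Rv1, the largest residual was 6.04e-05, 0.00592 and 1.07e-04 log2 units. The tolerance for the later steps, 2e-04, 0.006 and 3.22e-04 log2 units, was set from these residuals with a limit of 0.006. Whole reads were found for 100% of the regions with p above 0 in HPr1AR, 98.5% in LNCaP and 95.6% in 22Rv1. More than 1 pair of counts met the rule in 766, 10807 and 376 of these regions, and the pair nearest to the deposited fold was taken. After a random shift of the folds, counts were still found for 0.941%, 14.6% and 1.27%, so single LNCaP counts are the least certain. For the others (8613 regions in HPr1AR, 8301 in LNCaP and 3541 in 22Rv1) the smallest reads that reach the deposited p-value were taken. Where p was 0 (8613, 6737 and 135 regions), the ratio is then a lower bound. In 1564 regions of LNCaP and 3406 of 22Rv1 p was above 0 and no pair of counts met the rule. Their ratio is a lower bound only if the formula holds for them, which was not shown. A region of either kind is called higher where the bound suffices and is undetermined otherwise (85, 1477 and 63 regions). Reads were set against the rebuilt depths with an exact binomial test, two-sided, adjusted by Benjamini-Hochberg within a line at 0.05. These depths were derived from the fitted constants, on the assumption that each prior scales with depth. They were not checked against sequenced reads, and every read ratio rests on them. This ordinary read ratio was added after the data were seen. Printed read ratios carry 95% exact binomial intervals, and a count of 0 was set to a floor of 3 reads per pull-down.

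The steps were tested on simulated data of 6000 regions per line with 200 changed regions per size. Rebuilt reads were exact in 99.95% of simulated regions of HPr1AR, 96.7% of LNCaP and 99.9% of 22Rv1. Unchanged regions were called in 0.0769%, 0.0577% and 0.0769%. The simulation drew reads for 1 window per region from the fitted formula and depths, with no choice among windows. These shares therefore cannot show that the formula holds, nor how often unchanged regions of the real data were called. Regions changed by a log2 ratio of 4 were called in 70.4%, 63.1% and 68.8%, and those changed by a log2 ratio of 1 in 1.50%, 5.50% and 8.50%, so that a region not called higher is not shown to be unchanged.

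Gene names came from the deposited tables, and older symbols were matched through a RefSeq name table of assembly GRCh38.p14, used for names only; 99.2%, 99.1% and 99.2% of names matched in HPr1AR, LNCaP and 22Rv1. Region positions did not match the GRCh38 gene spans, so no coordinate of that table is printed and no sequence motif, stop codon or untranslated region was examined. Exon regions of a single gene were placed by the other exon regions of that gene within 10000 bp, with intron share and position classes taken from the authors' marks.

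Passing regions were compared with the rest by Fisher's exact test, regions of 2 lines by overlap of at least 1 bp, and folds by Spearman's rho across overlapping regions. Genes were compared by Fisher's exact test and the exact McNemar test. The 22 gene lists were fixed before the data were examined and tested in every line and in every pair of lines, 66 tests each, adjusted by Benjamini-Hochberg, with 10000 draws of genes with as many regions as the matched background. The named genes were set beforehand: per line the 8 genes with the smallest adjusted p and the 6 with the largest fold among regions under 0.01, 3 genes with lower signal, per pair and direction 6 genes passing in 1 line with no region under 0.5 in the other, the 6 genes with the smallest worst adjusted p over the lines, and up to 4 genes per list. Genes ranked by the adjusted p of the ordinary ratio were added later. Some genes that meet these rules are not reported here.

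Alternatives were an adjusted p of 0.01 or 0.1, a log2 fold of 1, a width of 100 bp, merging of regions within 100 bp, reciprocal overlap of 50%, equal numbers of top regions, exon overlap for genes, and a matched background. Added after the data were seen were the ordinary read ratio, a shared read rate and undetermined genes counted as higher. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.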

Results

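RNA carrying N6-methyladenosine (m6A), a modified base of messenger and non-coding RNA, was pulled down with an antibody against m6A and sequenced in 3 prostate cell lines, with a pull-down by unspecific immunoglobulin G (IgG) as the background. HPr1AR is a non-malignant prostate epithelial line that expresses the androgen receptor, LNCaP is an androgen-responsive line from a prostate cancer metastasis, and 22Rv1 is a prostate cancer line that grows at castrate androgen levels. The labels give 17 samples in 6 groups, with 3 samples of each pull-down in HPr1AR and LNCaP, 3 IgG samples in 22Rv1 and 2 m6A samples in 22Rv1; whether the m6A sample of 22Rv1 with replicate number 2, which is not among the labels, entered the table of that line is not known. The files used here hold 1 table of regions per line and no value per sample, so no spread between samples can be given. The constants fitted to the tables give a depth over both pull-downs of 16.8 M reads in HPr1AR, 12.8 M in LNCaP and 8.12 M in 22Rv1. In the same order, the numerator depth was 5.13, 3.92 and 3.30 M and the reference depth 11.7, 8.87 and 4.82 M. Read ratios are taken relative to these depths, and intervals from the rebuilt reads cover counting error only. Coordinates are printed as the files give them, and the submitters' processing notes name hg38. Yet only 14.3% of the gene and region pairs of HPr1AR, 14.8% of LNCaP and 13.8% of 22Rv1 lay inside their gene's GRCh38 span. Regions also ran past the last GRCh38 gene on 15, 15 and 14 chromosomes. These values argue against GRCh38 coordinates, and which other build they follow was not examined.

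The first question was which transcripts carry regions with more reads in the m6A pull-down than in the IgG pull-down of the same line. In HPr1AR the leading genes were SENP8, which encodes the NEDD8-specific protease, the Wnt receptor gene FZD1, and a stretch of the protocadherin gamma cluster shared by PCDHGA1, PCDHGA2, PCDHGA3, PCDHGA4, PCDHGA10 and PCDHGA11. In LNCaP they were the Hedgehog pathway kinesin gene KIF7 with its neighbour TICRR, SETMAR with SUMF1, the histone methyltransferase gene SETD1A, ARHGAP8 with the readthrough gene PRR5-ARHGAP8, and SYNJ2. In 22Rv1 they were GFOD1, the receptor kinase ligand gene GAS6, RPUSD2, LRFN1, ZNF696, GADD45G, RTEL1 and the readthrough gene RTEL1-TNFRSF6B, with CELSR3 added by the size of the deposited fold. The authors' deposited table listed each of these regions as up, with the adjusted p of SENP8, KIF7 and GFOD1 listed at 0. The authors' deposited table holds a p of 0 for 8613 regions of HPr1AR, 6737 of LNCaP and 135 of 22Rv1, so this order rests on the deposited fold. By the adjusted p of the ordinary ratio, a choice made after the data were seen, the smallest values included those of GCNT4 and METTL15 in HPr1AR (58 numerator reads against 0), SPSB1 in LNCaP (61 against 0) and ADGRL2 and ITGA9 in 22Rv1 (63 against 0). Regions with a p of 0 enter that order with their smallest counts and may belong above these.

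The SENP8 region of HPr1AR lay on chromosome 15 from 72431901 to 72433320 in an exon, and held at least 49 numerator reads and 0 reference reads. With the reference set to a floor of 3 reads, its log2 read ratio was at least 5.22 (95% exact lower limit 4.87, taken at 0 reference reads). The KIF7 region of LNCaP, on chromosome 15 from 90170321 to 90174170, held at least 51 numerator reads and 0 reference reads, which gives a log2 read ratio of at least 5.26 at the same floor (lower limit 4.91). The GFOD1 region of 22Rv1, on chromosome 6 from 13363501 to 13365900, held at least 45 numerator reads against 0, a log2 read ratio of at least 4.45 (lower limit 4.10). The headers do not say which pull-down is the numerator, so "higher" is used throughout for more reads in the numerator pull-down, taken after the names of the tables to be m6A.

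The authors' deposited table lists 139373 regions in HPr1AR, 110260 in LNCaP and 77311 in 22Rv1, every one of them up, with log2 folds between 14.56 and 31.50 in HPr1AR. Regions under the adjusted p of 0.05 in the authors' deposited table numbered 134462 in HPr1AR (96.5%), 105138 in LNCaP (95.4%) and 76773 in 22Rv1 (99.3%). These folds match a formula in which the reference log rate is subtracted 2 times. By that formula a region passes once it holds 1 numerator read. Folds of regions that did not pass fitted 0 numerator reads in 4911 of 4911 cases in HPr1AR. In LNCaP this was 5121 of 5122, and in 22Rv1 538 of 538. The rebuild gives 0 numerator reads only where p is high, and more only where p is low. No passing region could therefore receive 0. A region that did not pass could receive only 0 or no count, so these cases do not test whether 1 read suffices. Because 1 read suffices by that formula, the reads of each region's representative window were rebuilt. The ordinary ratio of numerator to reference rates was then tested with an exact binomial test, adjusted over the regions of a line. By that test 52944 regions were higher in HPr1AR (38.0%), 41834 in LNCaP (37.9%) and 41989 in 22Rv1 (54.3%). The representative window was taken to be the one that set the region's deposited p-value, which falls with numerator reads. No correction was made for the windows searched, so higher calls and ratios may run high and lower calls low. The median log2 read ratio was 1.26 in HPr1AR, 1.33 in LNCaP and 2.10 in 22Rv1. The tables start at different read rates, and above the rate shared by all 3 lines, 0.862 CPM (reads per M reads), the share of higher regions was 64.6% in HPr1AR, 60.8% in LNCaP and 55.2% in 22Rv1. An equal rate still means fewer reads in a shallower line, and the order of these shares follows depth. They do not show that 22Rv1 has the smallest share at equal power.

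GADD45G, a growth arrest and DNA damage gene, RTEL1, a helicase gene with a role at telomeres, RTEL1-TNFRSF6B, PPP1R3B, CCDC57 and GAS6 led the genes that passed in all 3 lines. The GADD45G region began at 92219931 on chromosome 9 in both HPr1AR and 22Rv1. Its log2 read ratio was at least 6.83 in HPr1AR (lower limit of the 95% exact interval 4.29, from 50 reads against 1), at least 5.29 in LNCaP (3.67, from 52 against 3) and at least 6.07 in 22Rv1 (3.52, from 46 against 1), where each pair of counts is the smallest the deposited values allow and no upper limit can be given. Ranked by the largest adjusted p of the ordinary ratio over the lines, a choice made after the data were seen, the genes higher in all 3 lines were led by the steroid sulfatase gene STS, PLEKHG2, AGK, RPL30, TPGS2 and ST3GAL2.

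Regions with fewer reads in the m6A pull-down than in IgG give the size of the reverse tail. The authors' deposited table lists them as up and no region as down. With the ordinary ratio, the reverse tail was led by SNORA12 inside CWF19L1, PRDX1, BZW1 and SCARNA18 in HPr1AR, PPA1, EIF3E, FOLH1 and CYP51A1 in LNCaP, and SCARNA5 inside ATG16L1, SREBF2, H2AC16 and IPO7 in 22Rv1. The counts of PPA1, EIF3E and CYP51A1 are not unique. These genes were named by their smallest adjusted p after the data were seen.

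In all, 127 regions were lower in HPr1AR, 111 in LNCaP and 580 in 22Rv1, which is 0.0911%, 0.101% and 0.75% of the lists. These counts may run low, because the p-value behind each representative window falls with numerator reads. SNORA12, a small nucleolar RNA, had 5 numerator reads against 76 reference reads and a log2 read ratio of -2.74 (95% exact interval -4.40 to -1.45). FOLH1, which encodes the prostate-specific membrane antigen, had an exon region in LNCaP with 9 reads against 65 and a log2 read ratio of -1.68 (-2.87 to -0.66). In 22Rv1 the cholesterol regulator gene SREBF2 had 5 reads against 38, a log2 read ratio of -2.38 (-4.08 to -1.03).

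Where regions lie along transcripts was compared because m6A is known to gather near stop codons and in long exons. Exon regions at the ends of genes were higher more often than internal exon regions in every line. Regions outside annotated genes and regions touching only a promoter were higher about as often as exon regions at the 5 prime end or more often, and intron regions of HPr1AR and LNCaP, with or without a promoter, were higher least often over the whole lists; above the shared read rate this turned in HPr1AR, where 66.3% of intron regions and 62.0% of exon regions were higher. Stop codons and untranslated regions are not marked in the tables, so the 3 prime end here means an exon region with other exons of its gene only upstream, within 10000 bp.

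**Figure D1:**
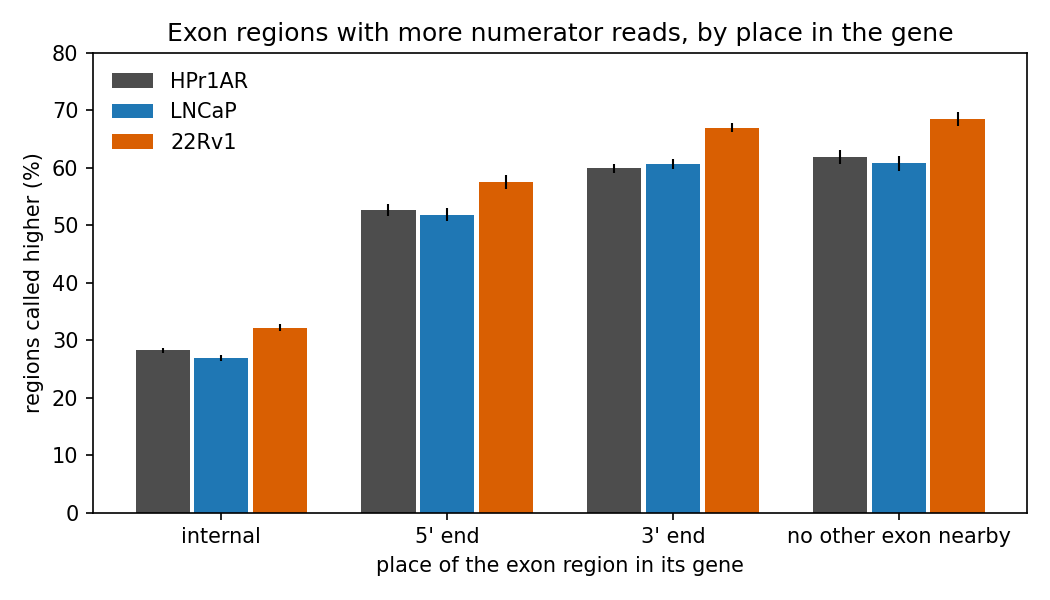
Percent of exon regions called higher (y axis) by place in the gene (x axis), 1 bar per cell line, with 95% Wilson intervals as lines. Internal regions lie between 26.8% and 32.2% and regions at the 3 prime end between 59.97% and 67.0%.

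At the 3 prime end 59.97% of 15163 exon regions were higher in HPr1AR, 60.7% of 13608 in LNCaP and 67.0% of 13408 in 22Rv1. Internal exon regions were higher in 28.2%, 26.8% and 32.2%, in the same order. At the 5 prime end the shares were 52.7%, 51.9% and 57.5%. End regions are wider (median 670 bp at the 3 prime end and 240 bp inside in HPr1AR), and width and reads raise the power of the test. Within bins of windows and reads, the odds of a 3 prime end region to be higher than an internal one were still 2.45 times in HPr1AR, 2.47 times in LNCaP and 2.77 times in 22Rv1. The same odds at the 5 prime end were 2.93, 3.01 and 2.70 times, above those of the 3 prime end in HPr1AR and LNCaP, and 3.75, 3.83 and 3.75 times for exon regions with no other exon nearby.

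**Figure D2:**
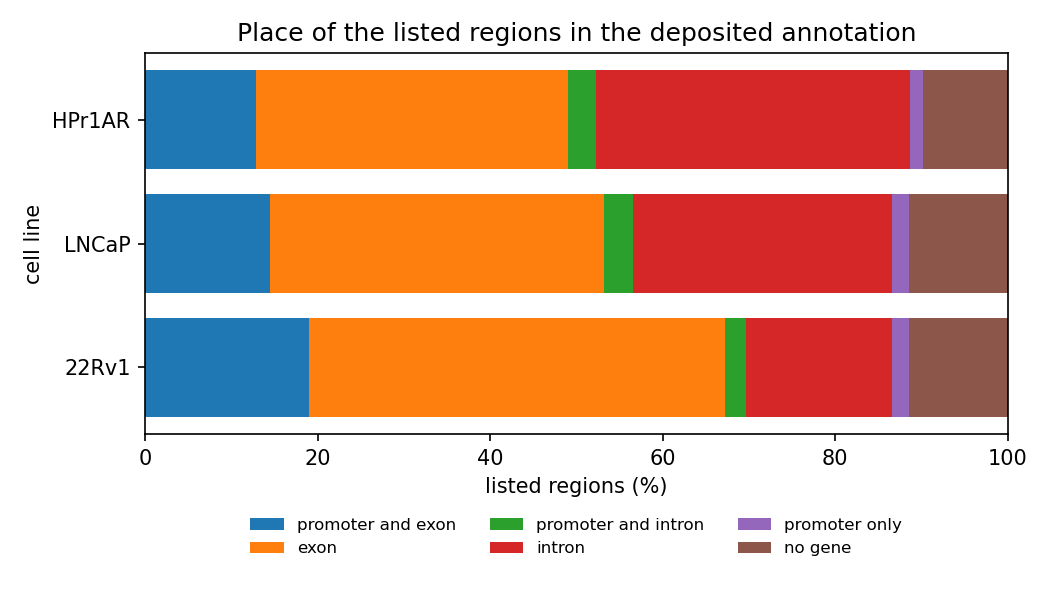
Percent of the listed regions (x axis) in each position class of the authors' annotation, 1 bar per cell line (y axis). Intron regions take 36.4% in HPr1AR, 30.1% in LNCaP and 16.9% in 22Rv1.

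Introns held 36.4% of the listed regions in HPr1AR, 30.1% in LNCaP and 16.9% in 22Rv1. By the deposited calls, intron regions made up less of the passing regions than of the others, with odds ratios of 0.301 in HPr1AR, 0.321 in LNCaP and 0.460 in 22Rv1 (Fisher's exact test, two-sided, p 6.49e-15 in 22Rv1). By the ordinary ratio 24.5% of intron regions were higher in HPr1AR, 24.9% in LNCaP and 56.7% in 22Rv1, and the odds ratio of 22Rv1 turned to 1.12. Above the shared read rate it was 1.09 in HPr1AR, 0.666 in LNCaP and 1.13 in 22Rv1. At that rate the intron share of the lists was 14.4%, 14.3% and 16.6%, so the gap between the lists did not hold at equal read rates. No reference sequence was used here, and the DRACH motif was not examined.

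The next question was how far the cell lines share their regions. The widely shared regions included those of GADD45G, whose region on chromosome 9 began at 92219931 in 2 of the lines, RTEL1, whose region from 62320481 to 62324830 on chromosome 20 was the leading region of the gene in both LNCaP and 22Rv1, and PPP1R3B, whose leading regions on chromosome 8 started at 8997411, 8996561 and 8996091.

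Of the passing LNCaP regions, 66.2% overlapped a passing HPr1AR region by at least 1 bp. Of the passing 22Rv1 regions, 77.4% overlapped one in HPr1AR and 78.5% one in LNCaP. A reciprocal overlap of 50% lowered these shares to 40.0%, 41.7% and 45.3%. They also depend on list length, and with the 76773 top regions of every line they were 64.3%, 66.6% and 71.1%. Using the regions higher by the ordinary ratio, the shares were 70.1%, 70.8% and 70.4%, again from lists of unequal length. Among overlapping regions, the odds ratio of being higher in both was 23.3 for HPr1AR and LNCaP, 25.1 for HPr1AR and 22Rv1 and 26.04 for LNCaP and 22Rv1. Calls depend on the number of reads, and these odds were not taken within bins of reads. They do not separate shared methylation from shared read levels. Across overlapping regions, Spearman's rho of the deposited folds was 0.739 for HPr1AR and LNCaP, 0.75 for HPr1AR and 22Rv1 and 0.769 for LNCaP and 22Rv1. The reference reads alone gave 0.668, 0.678 and 0.709, and these reads enter the deposited fold; regions are not independent replicates, and no p is given.

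At the level of genes, the comparison asks which transcripts are marked in 1 line and not in another. ABRAXAS1, FAM229B, SLC38A9, IFT52, STEEP1 and ANP32A-IT1 passed in HPr1AR with no region under 0.5 in LNCaP. ALKBH3-AS1, PARP16, RAB6D, GPC2, MIR3936 and TAS2R14 passed in LNCaP and not in HPr1AR. RAB6D, GPC2, PARP16, SLC7A2 and COX18 passed in 22Rv1 and not in HPr1AR, and VTRNA1-3, SCARNA3 and SATL1 in HPr1AR and not in 22Rv1. SCARNA3, SATL1, SNORA69 and VTRNA1-3 passed in LNCaP and not in 22Rv1, and POU5F2, TMEM14A, ABRAXAS1, TSPAN6 and SNORA58 in 22Rv1 and not in LNCaP.

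Many of these calls rested on few reads, and the difference between lines was not tested gene by gene. RAB6D stood out in LNCaP with 27 numerator reads against 2 and a log2 read ratio of 4.93 (95% exact interval 2.94 to 8.05), while HPr1AR listed it with 0 reads against 5. PARP16 had 16 reads against 1 in LNCaP, a log2 read ratio of 5.18 (2.49 to 10.57), and 0 against 9 in HPr1AR, where the listed region was another one, from 65551331 to 65551400 and not from 65578631 to 65580250 on chromosome 15. The median over the PARP16 regions of LNCaP was -1.60, the opposite direction. The amino acid transporter gene SLC7A2 had 44 reads against 3 in 22Rv1, a log2 read ratio of 4.42 (2.78 to 6.75), and only 1 reference read in HPr1AR. SCARNA3, a small Cajal body RNA gene, passed in HPr1AR although it held 1 numerator read against 18, a log2 read ratio of -2.98 (-8.36 to -0.32). STEEP1 and ANP32A-IT1 each had 5 reads against 6 in HPr1AR, so their ordinary ratios were not past the threshold.

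Genes with a passing region numbered 15300 in HPr1AR, 14561 in LNCaP and 14290 in 22Rv1, and 12696 genes passed in all 3. Among genes listed in both lines of a pair, nearly all passed in both, 13471 of 13495 for HPr1AR and LNCaP, and few were left for the exact McNemar test of passing (14 genes against 9 for HPr1AR and LNCaP, p 0.405; 3 against 5 for HPr1AR and 22Rv1, p 0.727; 4 against 5 for LNCaP and 22Rv1, p 1). By exon overlap, more genes passed in HPr1AR alone than in 22Rv1 alone (186 against 120, exact McNemar p 1.92e-04) and in LNCaP alone than in 22Rv1 alone (186 against 115, p 5.08e-05). By the ordinary ratio, 14140 genes had a higher region in HPr1AR, 13143 in LNCaP and 12917 in 22Rv1, and 10978 had one in all 3. Among genes determined in both lines, more were higher in HPr1AR alone than in LNCaP alone (554 against 313, exact McNemar p 2.33e-16), in HPr1AR alone than in 22Rv1 alone (687 against 250, p 8.83e-48) and in LNCaP alone than in 22Rv1 alone (528 against 354, p 5.11e-09), an order that follows the depth of the tables.

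Fixed gene lists were examined next, among them the androgen receptor and retinoid pathways that the study's title concerns, the m6A machinery, and abundant transcripts as a background. Androgen receptor target genes such as HERC3, PTGER4, ZBTB10 and ADAMTS1 and coregulator genes such as NCOA1, PIAS1, CTBP1 and EP300 were higher in every line where they were listed and their state could be determined. Retinoid genes led by RDH13, DHRS3, NR2F1 and NR2F2 were higher in nearly every case. Ribosomal protein genes and small structured RNA genes such as SCARNA2 and TERC stood below the other genes. Replication-dependent histone genes of determined state were higher in most cases in LNCaP and rarely in 22Rv1, as H2AC8 and H2BC8 were. H2BC15 and H2BC5 had a higher region in both lines.

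**Figure D3:**
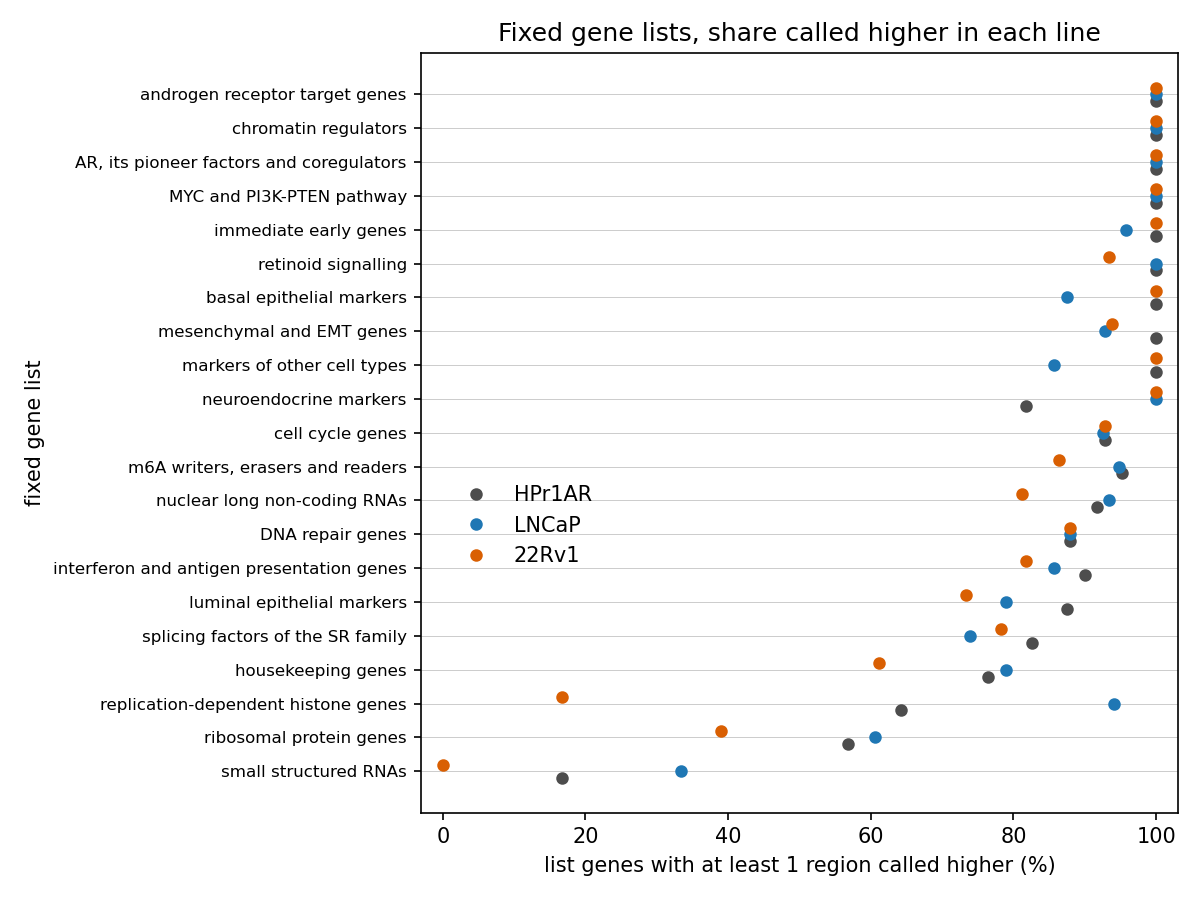
Percent of the determined genes of each fixed list (y axis) with at least 1 region called higher (x axis), 1 point per cell line. Lists of androgen receptor targets and chromatin regulators lie at 100%, and ribosomal protein genes lie between 39.0% and 60.5%.

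By the deposited calls every listed member of the 22 lists passed, and none of the 66 tests of a list in a line passed after adjustment, since nearly all genes passed. The mitochondrially encoded RNAs had 0 listed regions of 15 members. Whether the authors' counting included the mitochondrial chromosome was not examined, so this 0 does not bear on the methylation of these RNAs. By the ordinary ratio, 25 of 44 ribosomal protein genes were higher in HPr1AR (56.8% against 92.7% of the other genes, Fisher's exact test, adjusted p 1.65e-09), 23 of 38 in LNCaP (60.5% against 91.1%, adjusted p 5.35e-06) and 16 of 41 in 22Rv1 (39.0% against 90.8%, adjusted p 1.31e-14). Small structured RNA genes were higher in 1 of 6 in HPr1AR, 2 of 6 in LNCaP and 0 of 6 in 22Rv1 (Fisher's exact test, adjusted p 1.21e-04, 0.00621 and 7.48e-06), and the LNCaP call was lost against genes with as many regions (adjusted p 0.137). Housekeeping genes fell below the other genes in 22Rv1, with 11 of 18 higher (61.1%, adjusted p 0.00621), TPI1, HSP90AB1, YWHAZ and GUSB among the 11, and not past the threshold in HPr1AR (13 of 17) or LNCaP (15 of 19). All p of these lists were adjusted over the 66 tests.

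Of the determined histone genes, 27 of 42 were higher in HPr1AR (64.3%, Fisher's exact test, adjusted p 2.63e-06), 32 of 34 in LNCaP (94.1%, adjusted p 1) and 5 of 30 in 22Rv1 (16.7%, adjusted p 1.01e-19). A further 1, 4 and 8 listed histone genes were undetermined, in the same order. The 8 in 22Rv1 were among 38 undetermined genes of that line. Counted as higher, the undetermined genes gave shares of 65.1%, 94.7% and 34.2% (13 genes in 22Rv1, Fisher's exact test, adjusted p 1.71e-15). H2AC8 and H2BC8 share 1 region in each line, from 26215631 in LNCaP and from 26216461 in 22Rv1, both to 26217650 on chromosome 6. The LNCaP region held 53 numerator reads against 7, the smallest counts its deposited values allow, and the 22Rv1 region 42 against 68. The log2 read ratio was at least 4.10 in LNCaP (lower limit of the 95% exact interval 2.96) and -0.15 in 22Rv1 (95% exact interval -0.74 to 0.43). The representative windows of these overlapping regions may differ. Reads of near-identical histone genes may be split or shared between copies by the authors' counting, so single histone genes are uncertain.

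Every determined member was higher in the lists of androgen receptor targets (22, 25 and 22 genes in HPr1AR, LNCaP and 22Rv1), androgen receptor coregulators (21, 22 and 22), the MYC and PI3K pathway (24 in each line) and chromatin regulators (33, 32 and 31). The m6A writers, erasers and readers were higher in 20 of 21, 18 of 19 and 19 of 22 genes, led by YTHDC2, CBLL1, WTAP and RBM15B. WTAP, which encodes a subunit of the methyltransferase complex, had a log2 read ratio of 3.57 in 22Rv1 (95% exact interval 2.51 to 4.84). From the smallest counts the deposited values allow, it was at least 4.86 in HPr1AR (lower limit of the 95% exact interval 3.42) and at least 3.76 in LNCaP (2.73). The retinoid receptor gene RARG, named because of the study's title, had 30 numerator reads against 24 in HPr1AR, 16 against 3 in LNCaP and 29 against 7 in 22Rv1, with log2 read ratios of 1.51 (95% exact interval 0.69 to 2.35), 3.59 (1.79 to 6.01) and 2.60 (1.38 to 4.03). With all other genes as the background, no other list passed in any line, among them DNA repair genes with 22 of 25 higher in every line and cell cycle genes with 26 of 28 in HPr1AR.

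Between lines, the lists were compared by which members had a listed region at all, and by which were higher. The basal epithelial marker genes TP63, COL17A1, KRT5 and KRT14 had listed regions in HPr1AR and none in LNCaP or 22Rv1. The interferon genes OAS1 and IFI27 followed the same order. The androgen-regulated genes KLK3, KLK2 and TMPRSS2 had listed regions in both cancer lines and none in HPr1AR. KLK3, KLK2, TMPRSS2, TP63, KRT5 and KRT14 were named after their values were seen.

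All 23 basal epithelial markers had a listed region in HPr1AR, against 8 in LNCaP and 8 in 22Rv1, and no marker was listed in a cancer line alone (exact McNemar test, 15 against 0 in each pair, adjusted p 0.00201 in each). Interferon and antigen presentation genes were listed for 21 members in HPr1AR, 15 in LNCaP and 11 in 22Rv1, with an adjusted p of 0.0430 by the exact McNemar test for HPr1AR and 22Rv1 (10 against 0). That test takes an even split as no change, whereas over all genes the deeper HPr1AR table listed 2076 genes absent from 22Rv1, against 1060 the other way, and 1815 absent from LNCaP, against 1090. The mesenchymal genes, with 22 members listed in HPr1AR, 14 in LNCaP and 16 in 22Rv1, did not pass (exact McNemar test, adjusted p 0.129 and 0.344 against HPr1AR). A gene without reads gives no region, so these counts hold the level of the transcript as well as its methylation. For the androgen receptor targets as a list, no difference in listing passed between any pair of lines (exact McNemar test, adjusted p 1 for HPr1AR and LNCaP). KLK3 had 2 listed regions in LNCaP, neither called higher and the leading one undetermined, and 4 in 22Rv1, of which 3 were higher, with 44 reads against 3 in its leading region there.

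By the ordinary ratio the histone list differed between LNCaP and 22Rv1, with 20 genes higher in LNCaP alone and 0 in 22Rv1 alone (exact McNemar test, adjusted p 1.26e-04 over 66 tests). Between HPr1AR and 22Rv1 the counts were 12 and 0 (exact McNemar test, adjusted p 0.0161), and between HPr1AR and LNCaP 1 and 12 (adjusted p 0.0752). Counting genes of undetermined state as higher left the LNCaP and 22Rv1 comparison past the threshold (23 against 1, exact McNemar test, adjusted p 1.97e-04) and took away that of HPr1AR and 22Rv1 (13 against 2, adjusted p 0.162). For ribosomal protein genes no pair of lines passed after adjustment (10 against 2 for HPr1AR and 22Rv1, exact McNemar test, p 0.0386, adjusted p 0.636). A difference between lines is not excluded by this.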

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

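The histone test on a shift of all ratios and the counts with undetermined genes as higher were chosen after the result was seen; the test on read numbers was written before it.

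The basal epithelial markers differed between lines: 15 of 23 had a listed region in HPr1AR and none in LNCaP, and 15 had one in HPr1AR and none in 22Rv1 (exact McNemar test, adjusted p 0.00201 for each pair). The interferon and antigen presentation genes differed between HPr1AR and 22Rv1, with 10 members listed in HPr1AR alone and 0 in 22Rv1 alone (exact McNemar test, adjusted p 0.0430). The test takes an even split as no change, while over all genes listing leaned to the deeper HPr1AR table (2076 genes listed in HPr1AR alone against 1060 in 22Rv1 alone, 1815 against 1090 for LNCaP), so the interferon result in particular is weaker than its p reads. Both differences concern whether a gene has reads enough to be listed, and no test here separates the level of a transcript from its methylation. The higher calls of these lists did not pass between lines (exact McNemar test, adjusted p 1), but too few genes were split for the test to decide. For HPr1AR and LNCaP, 1 basal gene against 0 and 2 interferon genes against 0 were split.

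Replication-dependent histone genes differed in higher calls between LNCaP and 22Rv1 (20 genes against 0, exact McNemar test, adjusted p 1.26e-04) and between HPr1AR and 22Rv1 (12 against 0, adjusted p 0.0161). The HPr1AR difference did not hold when undetermined genes were counted as higher (adjusted p 0.162), so the weighing concerns LNCaP and 22Rv1.

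Fewer reads on histone genes in 22Rv1 were argued against as the whole cause: with LNCaP's ratios and 22Rv1's reads, 20.4 of the 26 genes determined in both lines would be called (SD 1.62), against 5 observed. LNCaP's ratios come from each gene's leading region and may run high, yet the ratio itself was lower in 22Rv1 in 23 of 26 genes. A shift of all ratios in 22Rv1 was also argued against, since the median difference was -0.017 over 13103 other genes and -1.13 over the histone genes (quartiles -2.81 and -0.66). Reads shared between histone copies, the number of m6A samples behind the 22Rv1 table, which is not known, and how much RNA without a poly(A) tail each library kept were not tested and remain open. A biological difference between the lines is a further open explanation, since the design gives the lines and no values per sample.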

How the results depend on the processing

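Alternatives named as ordinary read ratio, shared read rate and undetermined genes as higher were chosen after the data were seen; the others before the data were examined.

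Counts of passing regions were the same at an adjusted p of 0.01 or 0.1 because no region has a p between 0.001 and 0.9, and with a log2 fold of 1, because every log2 fold in the authors' deposited table is 14.03 or more; regions of 100 bp or more numbered 107721, 86744 and 62220 in HPr1AR, LNCaP and 22Rv1, and merging left 133103, 103768 and 76164. The ordinary read ratio lowered the counts to 52944 in HPr1AR, 41834 in LNCaP and 41989 in 22Rv1, by construction, since 1 numerator read no longer suffices. The shared read rate left 51490 passing regions in HPr1AR and 48823 in LNCaP. Lower regions rose from 0 to 127 in HPr1AR, 111 in LNCaP and 580 in 22Rv1 with the ordinary ratio.

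The intron odds ratio of 22Rv1 reversed to 1.12 with the ordinary ratio and to 1.13 at the shared read rate, and that of HPr1AR to 1.09 at the shared read rate; the cause was not tested beyond the read rate. In LNCaP it stayed under 1, at 0.416 and 0.666.

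For the overlap of regions, a reciprocal overlap of 50% gave 40.0% for HPr1AR and LNCaP, 41.7% for HPr1AR and 22Rv1 and 45.3% for LNCaP and 22Rv1, lower because the rule is stricter. Equal numbers of top regions gave 64.3%, 66.6% and 71.1%, and the ordinary ratio, with lists of unequal length, 70.1%, 70.8% and 70.4%; the cause was not tested. The correlation of folds became 0.782, 0.796 and 0.800 with the ordinary ratio. Counts of genes shared by pairs of lines stayed within 1.5 times under every alternative run. The exact McNemar tests of genes, not past 0.05 by the deposited calls, passed by exon overlap for HPr1AR and 22Rv1 (1.92e-04) and LNCaP and 22Rv1 (5.08e-05), with fewer genes in 22Rv1 alone, and not for HPr1AR and LNCaP (0.199). With equal numbers of top regions the test is void for pairs with 22Rv1, since the number is that of 22Rv1 and only the other list loses genes; HPr1AR, which loses more regions than LNCaP, had fewer genes alone there too (101 against 170, p 3.30e-05).

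Of the 66 list tests, 0 passed by the deposited calls and 9 by the ordinary ratio, 9 with a matched background and 9 with undetermined genes as higher; the matched background dropped small structured RNA genes in LNCaP (adjusted p 0.137) and added SR splicing genes there (adjusted p 0.00377).

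Among single genes with a called ratio, the median over a gene's regions reversed the log2 read ratio of SLC38A9 in HPr1AR (-0.20) and PARP16 in LNCaP (-1.60). The sign also turned for uncalled ratios, those of FAM229B (-0.51), IFT52 (-0.34), STEEP1 (-0.08) and ANP32A-IT1 (-0.34) in HPr1AR and of TMEM14A (-0.94) and TSPAN6 (-0.24) in 22Rv1.

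No paired analysis was possible because the tables carry no column per sample. For the same reason leaving out a replicate, the replicate block, DESeq2 size factors and a low-count filter were not run. The motif alternatives (200 bp, GGAC) and the stop codon and untranslated classes were not run, since no sequence or matching annotation was used here. Regions with 1 to 3 numerator reads make up 28.8% of the passing regions in HPr1AR, 32.8% in LNCaP and 11.8% in 22Rv1, which does not follow depth.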

Other observations

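The tests on the fold column and on the intron share were chosen after the result was seen; those on small nucleolar RNA genes and zinc finger genes were written before the test was run.

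Small nucleolar and small Cajal body RNA genes appeared among the regions with fewer numerator reads (SNORA12, SCARNA18, SCARNA5), and a lower read ratio of the whole class was tested. In HPr1AR 42.5% of 207 such genes had a higher region, against 82.5% of other genes with as many listed regions. In LNCaP the shares were 33.3% of 210 genes and 80.1%, and in 22Rv1 19.7% of 188 and 82.7% (Fisher's exact test against all other genes, adjusted over 21 tests, p 2.82e-79, 6.97e-95 and 4.90e-120). A lower m6A signal of this class may explain the pattern, and so might the shortness of these RNAs, which was not tested.

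Zinc finger genes of the ZNF series went the other way, as ZNF696 and ZNF184 did in 22Rv1. The share with a higher region was 98.9% of 468 genes in HPr1AR, 98.2% of 496 in LNCaP and 99.4% of 499 in 22Rv1, against 92.3%, 90.8% and 89.8% of other genes with as many regions (Fisher's exact test against all other genes, adjusted p 2.91e-10, 5.27e-11 and 2.99e-17). Longer exons or a higher m6A signal could give this; neither was separated.

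Every region of the authors' deposited table is up with log2 folds above 14. In the line with the lowest value, 100% of the fitted 1-window regions lay on the whole-number grid of a doubled reference. The tolerance came from the residuals of this same grid, so the 100% was fixed in advance in HPr1AR and 22Rv1. What bears on the grid is that after the folds were displaced at random at most 3.18% lay on it, in LNCaP. The ordinary grid below was judged at the same tolerance. The grid of an ordinary ratio held 1.87% in HPr1AR, 84.2% in LNCaP and 20.7% in 22Rv1, and 3.51%, 78.2% and 26.7% after displacement. A first rule, that the ordinary grid hold under 50% in every line, was not met in LNCaP, where steps of 1 read are narrower than the tolerance; the displaced folds were added then. Ratios of that size with 1 reference read per region would need at least 1286 M numerator reads in 22Rv1 at the smallest fold, above the 40 M aimed at per sample, which argues against them. A contrast with the reference coefficient entered 2 times is a candidate explanation.

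Intron regions made up more of the lists of HPr1AR (36.4%) and LNCaP (30.1%) than of 22Rv1 (16.9%), a largest gap of 19.5 percentage points. At the shared read rate the largest gap between lines was 2.32 points and ran the other way, with 16.6% in 22Rv1 against 14.4% in HPr1AR and 14.3% in LNCaP. Different read rates at which the lists start may account for the excess in HPr1AR and LNCaP.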
